A study of Mus musculus with 12 samples.

How the data were processed

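RNA was measured in mouse embryonic stem (ES) cells of 2 genetic backgrounds, 129 and B6J, all labelled male. B6J is read here as the C57BL/6J background. The cells were kept in medium with serum and leukaemia inhibitory factor (LIF), and received either the solvent DMSO or 1 µM of the MEK inhibitor PD 0325901 each day until day 5, per the labels' protocols. MEK is the kinase that activates ERK, and its inhibitor is a component of the usual naive ("2i") culture media. Total RNA was extracted with Trizol, libraries were made with a stranded polyA kit (TruSeq Stranded mRNA), and sequencing was on a NovaSeq 6000. Each of the 4 groups (129 with DMSO, 129 with the inhibitor, B6J with DMSO, B6J with the inhibitor) held 3 libraries, 12 in all. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values given here measure only the spread between these libraries, which may be technical. The labels name 1 genotype per background and no clone, so a difference between backgrounds cannot be told apart from a difference between the cell lines used.

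The values are whole-number read counts per gene, deposited by the authors as 1 table of 26742 genes with Ensembl identifiers for the 12 libraries, without normalization. The submitters' processing notes name STAR 2.7.10, SAMtools, HTSeq 0.6.1p1 and DESeq, and the builds mm10 and GRCm38, with no role or order. The annotation, the strand setting of the counting and the treatment of reads with several positions are not given in the sources used here. Gene symbols, positions and biotypes were taken from GENCODE M21 on GRCm38, in which 26725 of the identifiers were found; positions are 1-based. Of the genes, 21775 had a count in some library. Values from 1 to 20 were even in 70.09 to 73.37% of cases per library, against 52.06 to 55.17% of values from 101 to 1000, so most low values are multiples of 2, and halved counts were tried as an alternative. All 13 mitochondrial genes of the table hold 0 counts in every library. Because of these limits, genes that share sequence with near-identical copies (the Zscan4, Pramef, Xlr and Rhox families, MHC class I genes, single-exon copies of other genes), overlapping genes and antisense pairs are uncertain: the counting may have split or dropped their reads.

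Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr for the 4 groups (min.count 10, min.total.count 15) were kept, which left 16627. Libraries were scaled by TMM, and all 12 entered 1 quasi-likelihood fit (glmQLFit, glmQLFTest) with 4 group means, so that the groups share an estimate of the spread. The 5 contrasts were the response to the inhibitor in 129, the response in B6J, the difference between these responses (B6J minus 129, an interaction term), and the difference between backgrounds (B6J minus 129) in DMSO and in the inhibitor. A gene was called at a Benjamini-Hochberg adjusted p under 0.05; every adjusted p of a single gene is from this test unless another tool is named. Levels are CPM (read counts scaled to a common library total adjusted by TMM), as mean ± SD over 3 libraries. A fold against a group with no counts is given only as a lower bound, against a floor of 3 counts over the group; floors cover counting error only.

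There were 27 gene lists, fixed with the contrasts, tests, alternatives and the rule for named genes before the data were examined. They covered MEK/ERK feedback and immediate early targets, naive, core, and formative and primed pluripotency, DNA methylation writers and maintenance, DNA demethylation, imprint protection and KRAB zinc finger silencing, imprinted genes, methylation-sensitive germline genes, 2-cell-like genes, primitive endoderm, mesoderm and primitive streak, neuroectoderm, trophoblast, fibroblast (feeder cell) markers, cholesterol synthesis, glycolysis, complex I, ATF4 and amino acid stress, p53 targets, G1/S cell cycle, Wnt targets, interferon and viral mimicry, Hox genes as bivalent developmental regulators, polycomb, KRAB zinc finger cluster genes and MHC class I. Each list was tested in each contrast with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over all 135 list tests. Of these, 45 were called. With a correlation estimated from the data, 0 of the 135 were called; 12 libraries in 4 groups give an imprecise estimate of that correlation. For lists described in a comparison the text gives how many members passed the test over all genes, and how many passed when adjusted over the list alone. An adjusted p of a list is from camera unless fry is named.

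The text names genes by these rules. For each contrast it may name the 5 genes with the largest rise and the 5 with the largest fall among called genes with a mean of at least 5 CPM in the higher group and no overlap of libraries (for the interaction, the same sign for every pairing of replicate numbers), leaving out provisional names. The text may also name up to 4 tested members of each list with the smallest p, 15 genes of ERK signalling, pluripotency and DNA methylation chosen in advance, and, as checks on the labels, Nnt, Xist and Y-linked genes. Other genes are named only where a list has few called members or a library is singled out; these were chosen after their values were seen. The result of 1 single gene is not reported here.

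The test was tried on simulated data made from the real means, spread and library sizes, in which 100 genes were changed by 2-fold and 100 by 4-fold. Recovered were 77 and 95 of 100 for the 129 response (11 of 16158 unchanged genes called), 77 and 95 for B6J (5 of 16167) and 67 and 89 for the interaction (7 of 16178). Between backgrounds it was 70 and 98 in DMSO (9 of 16179) and 72 and 97 in the inhibitor (5 of 16180).

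Replicate numbers come from the sample titles. After subtracting group means, 129 libraries with the same number correlated across genes with r of 0.442, 0.295 and 0.222 (numbers 1, 2 and 3), all above the limit of 0.1 set in advance, so the numbers pair the 129 libraries; numbers of B6J libraries and numbers across backgrounds did not pair. A fit with the number as a block is given beside a result for 129 or for the difference in response where it changes the call, and for other comparisons only among the alternatives. All pairs of replicates differed by far more than sampling noise (chi-square per degree of freedom of 6.909 to 174.5 over genes with at least 10 summed counts), so no library was counted as a copy of another. The alternatives fixed in advance were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter (at least 1 CPM in at least 6 libraries), a fit of the compared groups alone, an adjusted p under 0.01, a minimum log2 fold change of 1, the replicate block, and leaving out each library in turn. Added after seeing the data were a covariate holding each library's mean of the fibroblast markers (the fibroblast covariate), leaving out both 129 libraries numbered 1, and halved counts. The covariate rose with the inhibitor and is partly confounded with it.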

Results

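Gene expression was measured in mouse ES cells of the 129 and the B6J background after 5 days in serum and LIF with either DMSO or the MEK inhibitor, with 3 libraries in each of the 4 groups. The series title concerns genetic variation and the loss of DNA methylation in naive pluripotent cells, so the design asks what MEK inhibition changes in each background, whether the 2 backgrounds respond differently, and how they differ in each medium. Library totals ran from 62634533 to 73031809 counts in 129 with DMSO and from 65564142 to 82701438 in 129 with the inhibitor. In B6J they ran from 74164171 to 82505523 with DMSO and from 81310810 to 96341637 with the inhibitor. In each group 1 library differed more from the others than they from each other, by chi-square per degree of freedom. Replicate 1 of 129 with DMSO gave 174.5 and 165.6 (7.502 between the others) and with the inhibitor 84.99 and 69.64 (15.69). Replicate 1 of B6J with DMSO gave 88.84 and 85.23 (6.909), and replicate 3 with the inhibitor 120.4 and 42.13 (26.34). Nnt, which carries a deletion in C57BL/6J mice, was not lower in B6J (log2 difference from 129 of 0.71 in DMSO and 0.55 in the inhibitor, adjusted p = 0.0464 and 0.121).

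In 129 cells given the MEK inhibitor most of the tested ERK targets fell and most of the naive pluripotency genes rose. Egr1, an immediate early transcription factor, fell from 261 ± 63 to 8.19 ± 1.87 CPM (SD, n = 3), and Dusp6, a phosphatase that acts on ERK, fell from 91.6 ± 10 to 26.7 ± 0.726 CPM (SD, n = 3). Tbx3, a naive pluripotency factor, rose from 82.7 ± 8.56 to 258 ± 26.2 CPM, and Prdm14, which represses the de novo methyltransferases, rose from 11.9 ± 3.66 to 42.6 ± 4.99 CPM. Fgf5, a marker of formative and primed cells, fell from 41.1 ± 4.78 to 1.12 ± 0.393 CPM. There were 5930 genes differentially expressed, 2899 higher and 3031 lower.

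Of the 26 tested MEK/ERK feedback and immediate early genes, 18 fell and 0 rose in 129 (18 and 0 adjusted over the list alone), with a median log2 fold change of -1.003 (camera adjusted p = 2.4e-08; adjusted p = 0.585 with an estimated correlation). Egr1 changed by -5.00 (SE 0.23, adjusted p = 1.88e-07), Dusp6 by -1.78 (SE 0.085, adjusted p = 2.38e-07) and the phosphatase Dusp4 by -2.54 (SE 0.14, adjusted p = 4.78e-07). Of 20 naive genes 18 rose and 0 fell (18 and 1 adjusted over the list alone; median 0.73, adjusted p = 7.05e-08; adjusted p = 0.585 with an estimated correlation). The median was 1.24 with the fibroblast covariate. Log2 fold changes were 1.64 (SE 0.095, adjusted p = 5e-07) for Tbx3, 1.85 (SE 0.20, adjusted p = 4.76e-05) for Prdm14, 0.70 for Klf4 and 0.68 (SE 0.17, adjusted p = 0.0107; 1.40 with the covariate) for Nanog. Of 23 formative and primed genes 17 fell and 1, Foxd3, rose (17 and 2 adjusted over the list alone; median -0.98, adjusted p = 1.91e-06; adjusted p = 0.585 with an estimated correlation). Among these, Fgf5 changed by -5.20 and the POU factor Pou3f1 by -2.68. Of 14 core pluripotency genes 6 rose and 1, Lin28a, fell, the same numbers adjusted over the list alone (median 0.20, adjusted p = 0.0824). The list was called with the covariate (0.54, adjusted p = 0.00283) and without replicate 2 or 3 of 129 with DMSO or replicate 1 with the inhibitor (adjusted p = 0.0484, 0.0383 and 0.0447). Sox2 rose by 0.66 and Fgf4 by 1.24, while Pou5f1 was at 766 ± 93.6 CPM in DMSO and 887 ± 13.6 CPM in the inhibitor (log2 fold change 0.21, adjusted p = 0.0906; 0.0329 with the covariate).

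The DNA methylation machinery changed in both directions in 129. Dnmt3b, a de novo methyltransferase, fell from 723 ± 78.3 to 278 ± 24.8 CPM (log2 fold change -1.38, SE 0.10, adjusted p = 2.34e-06), whereas Dnmt3l, its catalytically inactive partner, rose from 160 ± 38.6 to 293 ± 49.1 CPM (0.88, SE 0.17, adjusted p = 0.0022; 0.28, adjusted p = 0.197 with the fibroblast covariate). Dnmt3a, the other de novo enzyme, was at 164 ± 32.3 and 122 ± 21.9 CPM (-0.42, SE 0.16, adjusted p = 0.0588). It passed the test without replicate 1 of 129 with DMSO (-0.58, adjusted p = 0.00657) and with the replicate number as a block (adjusted p = 0.00609). Uhrf1, which brings Dnmt1 to newly replicated DNA, rose from 364 ± 11.2 to 533 ± 43.4 CPM (0.55, SE 0.077, adjusted p = 0.000252), and Uhrf2 fell by 0.77. The maintenance enzyme Dnmt1 was at 385 ± 2.28 and 404 ± 48.4 CPM (0.07, adjusted p = 0.553). Without replicate 1 of 129 with the inhibitor its adjusted p was 0.0372, at a log2 fold change of 0.17. Of 14 methylation writers 3 rose (Uhrf1, Dnmt3l, Mat2a) and 3 fell (Dnmt3b, Uhrf2, Ahcy), with 3 and 4 adjusted over the list alone and a camera adjusted p of 0.939. Of 16 demethylation genes 5 rose (Prdm14, Apex1, Dppa3, Gadd45a, Gadd45g) and 5 fell (Tdg, Cxxc4, Neil2, Tet3, Neil3), with 6 and 6 adjusted over the list alone (adjusted p = 0.911). The oxidases Tet1 and Tet2 had log2 fold changes of 0.11 and 0.42 (adjusted p = 0.722 and 0.279).

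In 129 Zfp57, a zinc finger protein that binds methylated imprinting control regions, rose by 0.99 on the log2 scale (SE 0.095, adjusted p = 1.65e-05), the histone methyltransferase Setdb1 by 0.57 and its partner Trim28 by 0.59, while Suv39h1, another histone methyltransferase, fell by 1.38. Of the 18 genes of imprint protection 5 rose (Zfp57, Setdb1, Trim28, Daxx, Dppa3) and 4 fell (Suv39h1, Smchd1, Ehmt1, Suv39h2), with 6 and 5 adjusted over the list alone (camera adjusted p = 0.726). Of 60 imprinted genes 10 rose and 20 fell (12 and 23 adjusted over the list alone; adjusted p = 0.117). Dio3, which inactivates thyroid hormone, rose by 2.95 (adjusted p = 1.88e-07), and Magel2 and Peg10 changed by -3.43 and -2.002. Of 47 germline genes known to be silenced by methylation 13 rose and 4 fell (Tdrkh, Tdrd1, Spo11, Ddx4), the same numbers adjusted over the list alone. Their median was 0.29 (adjusted p = 0.0236; adjusted p = 0.825 with an estimated correlation). That call was lost without replicate 1 of 129 with DMSO (adjusted p = 0.0747) and without replicate 2 or 3 of 129 with the inhibitor (0.0752 and 0.071) and with the stricter filter (0.0865), and the median lay at 0.50, 0.47 and 0.54 without replicate 1, 2 or 3 of 129 with DMSO and at 0.48 without replicate 1 of 129 with the inhibitor. It was 0.65 with no filter, 0.67 (adjusted p = 0.00575) without both 129 libraries numbered 1 and 1.04 (23 higher, adjusted p = 3.47e-06) with the covariate. The homeobox genes Rhox6 and Rhox9 rose by 1.89 and 1.76, with reads that may be shared within their family.

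In 129, 11 of 17 mesoderm and primitive streak genes fell and 3 rose. Lhx1, a transcription factor of the anterior primitive streak, went from 20.2 ± 5.31 to 0.216 ± 0.147 CPM (log2 fold change -6.55, SE 0.46, adjusted p = 1.97e-06), T (Brachyury) from 120 ± 23.4 to 3.40 ± 1.95 CPM (-5.14) and Eomes from 31.4 ± 3.42 to 3.86 ± 0.754 CPM (-3.02). Of 17 genes of mesoderm and primitive streak 11 fell and 3 (Kdr, Bmp4, Foxf1) rose, with 11 and 4 adjusted over the list alone and a median of -1.58 (camera adjusted p = 0.000629; adjusted p = 0.585 with an estimated correlation). Of 18 primitive endoderm genes 9 fell and 0 rose (10 and 0 adjusted over the list alone), but the list was not called (median -2.13, adjusted p = 0.187; 0.0301 without replicate 2 and 0.023 without replicate 3 of 129 with DMSO). Its median was 0.10 (adjusted p = 0.445) without replicate 1 of 129 with DMSO, and without both 129 libraries numbered 1 there were 8 higher and 6 lower. DESeq2 called 2 lower and limma-voom 1, and with the covariate the median was -4.15 (adjusted p = 1.59e-07). These genes were concentrated in 1 library: Gata6, their lead transcription factor, was at 33.9 CPM in replicate 1 of 129 with DMSO and at 3.18 and 2.97 CPM in replicates 2 and 3. Its log2 fold change of -2.45 (adjusted p = 0.0267) became -0.33 (adjusted p = 0.217) without that library, and its adjusted p was 0.0629, 0.0783 and 0.0865 without replicate 1, 2 or 3 of 129 with the inhibitor, 0.0889 with the replicate number as a block, 0.175 with limma-voom, 0.101 in a fit of the 129 groups alone and 0.0779 without both 129 libraries numbered 1. Of 16 MHC class I antigen presentation genes 13 fell and 0 rose (13 and 1 adjusted over the list alone; median -1.76, adjusted p = 1.99e-06; adjusted p = 0.585 with an estimated correlation). The median was -1.15 with the covariate. H2-K1 went from 59.7 ± 16.3 to 13.5 ± 0.572 CPM, Tap2, a peptide transporter, changed by -2.49 and its partner Tapbp by -1.03. Of 23 cholesterol synthesis genes 16 fell and 0 rose (17 and 0 adjusted over the list alone; median -0.48, adjusted p = 3.63e-05; adjusted p = 0.596 with an estimated correlation). Among the lists with 0 genes called in 1 direction by edgeR in 129, that direction held 1 naive and 1 MHC class I gene and 0 of the MEK/ERK, primitive endoderm, cholesterol and fibroblast genes at an unadjusted p under 0.05. DESeq2 called 1 of these (MHC class I) and limma-voom 0.

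Prelp, a matrix proteoglycan, rose in 129 from 1.00 ± 0.774 to 25.4 ± 7.81 CPM (log2 fold change 4.65, SE 0.46, adjusted p = 2.08e-05) and the collagen Col10a1 by 4.05. Of the 20 fibroblast (feeder cell) markers 15 rose and 0 fell (18 and 0 adjusted over the list alone; median 1.06, camera adjusted p = 2.43e-05; adjusted p = 0.744 with an estimated correlation). Col1a1 was at 792 ± 302 and 2176 ± 637 CPM (1.46) and decorin (Dcn) rose by 2.19. Of 31 Hox genes 12 rose and 1, Hoxb1, fell (15 and 1 adjusted over the list alone; median 0.82, adjusted p = 0.000214; adjusted p = 0.687 with an estimated correlation), and Hoxc6 rose by 1.54. The mean log2 CPM of the fibroblast markers was 6.36, 5.41 and 5.35 in replicates 1 to 3 of 129 with DMSO and 7.25, 6.62 and 6.67 with the inhibitor, and that of the Hox genes 0.07, -0.49 and -0.40 against 0.75, 0.41 and 0.36. With the fibroblast covariate, the Hox median in 129 was -0.13 (adjusted p = 0.878) and that of the cholesterol genes -0.19.

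**Figure D1:**
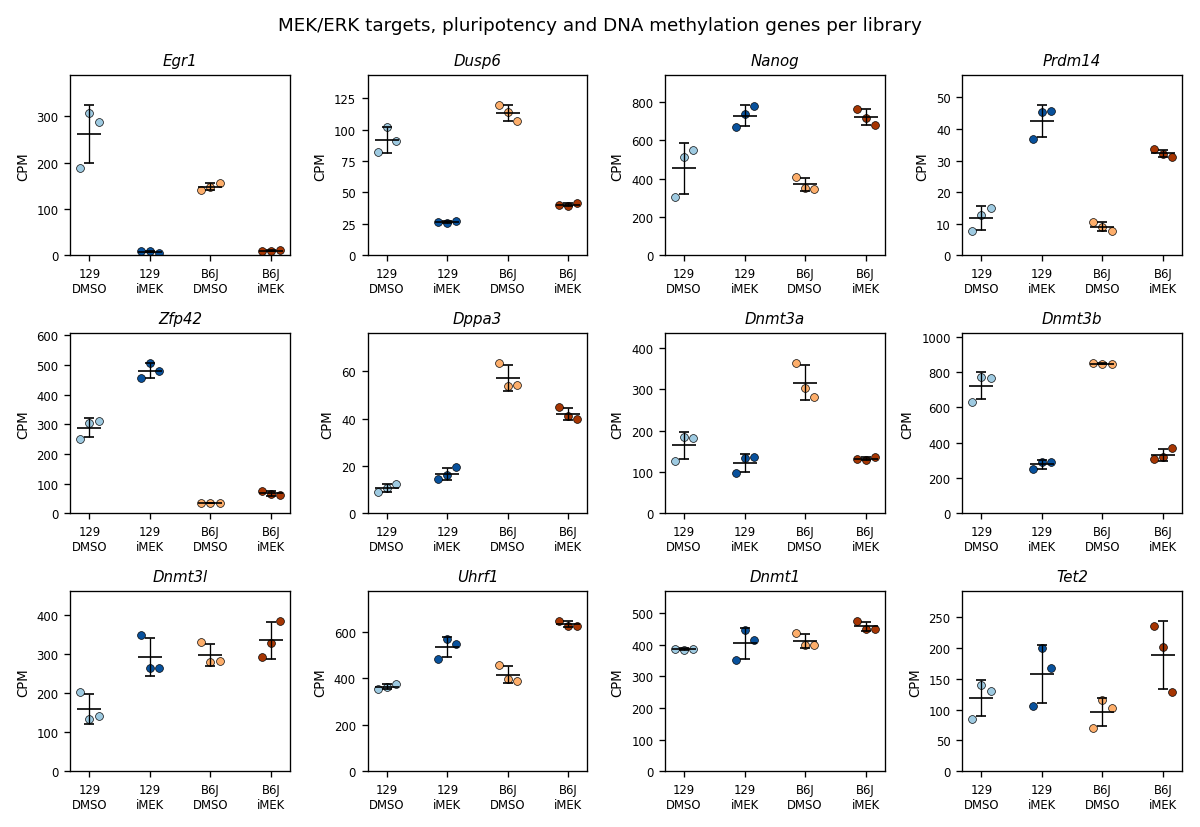
Each panel shows 1 gene, with CPM on a linear y axis and the 4 groups on the x axis; points are libraries, the horizontal bar is the mean and the error bar the SD of 3 libraries. In both backgrounds Egr1, Dusp6 and Dnmt3b are lower and Prdm14, Zfp42 and Uhrf1 higher with the inhibitor, while Zfp42 is 289 CPM in 129 and 35.7 CPM in B6J with DMSO.

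In B6J cells most ERK targets fell and most naive genes rose. Egr1 fell from 149 ± 7.78 to 9.84 ± 1.37 CPM and Dusp6 from 113 ± 6.27 to 40.2 ± 1.34 CPM (SD, n = 3). Tbx3 rose from 41.3 ± 2.61 to 188 ± 2.90 CPM and Nanog from 370 ± 35.1 to 719 ± 40.9 CPM. Of 31 genes of the 2-cell-like state, a rare ES cell state resembling the 2-cell embryo, 20 rose from low levels. Both de novo methyltransferase genes fell. There were 5166 genes differentially expressed in B6J, 2423 higher and 2743 lower.

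Of the 26 MEK/ERK genes 22 fell and 0 rose in B6J (22 and 0 adjusted over the list alone; median -1.151, camera adjusted p = 9.14e-12; adjusted p = 0.503 with an estimated correlation). Log2 fold changes were -3.92 (SE 0.21, adjusted p = 6.46e-07) for Egr1, -1.49 (adjusted p = 7.74e-07) for Dusp6 and -1.68 for Spry4, a feedback inhibitor. Of 20 naive genes 17 rose and 2 (Gbx2, Dppa3) fell, the same numbers adjusted over the list alone. Their median was 0.93 (adjusted p = 1.05e-07; adjusted p = 0.585 with an estimated correlation). Tbx3 changed by 2.19 (SE 0.097, adjusted p = 2.1e-07), Prdm14 by 1.84 and Nanog by 0.96 (adjusted p = 0.00162). Of 23 formative and primed genes 12 fell and 2 (Foxd3, Otx2) rose, the same numbers adjusted over the list alone. Their median was -0.66 (adjusted p = 0.00192; adjusted p = 0.616 with an estimated correlation). Of 14 core pluripotency genes 5 rose and 2 (Lin28a, Utf1) fell, the same numbers adjusted over the list alone (adjusted p = 0.354; 0.0344 with the covariate), and Pou5f1 had a log2 fold change of 0.10 (adjusted p = 0.446).

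Dnmt3a fell from 316 ± 42.2 to 132 ± 3.93 CPM in B6J (log2 fold change -1.26, SE 0.16, adjusted p = 0.000142; -0.84 with the covariate) and Dnmt3b from 846 ± 3.62 to 332 ± 34.8 CPM (-1.35, adjusted p = 3.44e-06), while Dnmt3l was at 299 ± 28.5 and 336 ± 46.8 CPM (0.17, adjusted p = 0.492). Uhrf1 rose from 415 ± 36.9 to 633 ± 11.5 CPM (0.61, adjusted p = 0.000124), and Dnmt1 had a log2 fold change of 0.15 (adjusted p = 0.183). Of 14 methylation writers 4 rose (Uhrf1, Mat2a, Pcna, Lig1) and 3 fell (Dnmt3b, Dnmt3a, Ahcy), the same numbers adjusted over the list alone (camera adjusted p = 0.674). Of 16 demethylation genes 4 rose (Prdm14, Apex1, Tet2, Gadd45b) and 6 fell (Gadd45a, Tdg, Cxxc4, Dppa3, Tet3, Neil3), with 4 and 7 adjusted over the list alone (adjusted p = 0.756). Tet2 rose by 0.97 (adjusted p = 0.0246), a call lost without replicate 1 or 3 of B6J with DMSO or replicate 1 or 2 with the inhibitor (adjusted p = 0.0895, 0.0576, 0.0911 and 0.0758). Dppa3, a maternal factor that protects imprints and limits Uhrf1, changed by -0.45 (adjusted p = 0.0252), a call lost without replicate 1 of B6J with DMSO or replicate 2 or 3 with the inhibitor (adjusted p = 0.0886, 0.082 and 0.0847) and with the fibroblast covariate (-0.12, adjusted p = 0.523).

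Of the 18 genes of imprint protection 4 rose (Zfp57, Trim28, Daxx, Morc3) and 7 fell in B6J, the same numbers adjusted over the list alone (camera adjusted p = 0.627). Zfp57 rose by 1.02 (adjusted p = 1.44e-05). Of 60 imprinted genes 9 rose and 18 fell, the same numbers adjusted over the list alone (adjusted p = 0.093), with Dio3 at 3.51 and Peg10 at -2.68. Of 47 germline genes 13 rose and 5 fell (Tdrkh, Tdrd1, Ddx4, Taf7l, Sycp2), with 14 and 6 adjusted over the list alone (median 0.60, adjusted p = 0.103; 0.84, adjusted p = 0.000288 with the covariate). Xlr3a, an X-linked lymphocyte-regulated gene, rose by 4.10 (adjusted p = 5.09e-05) from 0.0344 ± 0.017 to 0.606 ± 0.255 CPM. Of 31 genes of the 2-cell-like state 20 rose and 0 fell (22 and 0 adjusted over the list alone; median 2.86, adjusted p = 2.2e-06; adjusted p = 0.744 with an estimated correlation), and limma-voom called 7 of them; with the covariate the median was 4.62. Among the lists with 0 genes called in 1 direction by edgeR in B6J, that direction held 2 MHC class I genes, 1 primitive endoderm gene and 0 of the MEK/ERK, 2-cell-like and fibroblast genes at an unadjusted p under 0.05. DESeq2 called 1 of these (MHC class I) and limma-voom 0. Pramel7 rose by 3.81, Pramel6 by 2.10 and Zscan4d, a telomere-associated zinc finger gene, by 3.31 (SE 0.73, adjusted p = 0.00524; 0.117 with limma-voom) from 0.181 ± 0.0458 to 1.81 ± 0.318 CPM. These families share sequence between members.

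Of 17 genes of mesoderm and primitive streak 7 fell and 1, Gsc, rose in B6J (9 and 2 adjusted over the list alone; median -0.81, camera adjusted p = 0.0099; adjusted p = 0.585 with an estimated correlation), with a median of -1.27 without replicate 2 of B6J with DMSO and -0.55 (adjusted p = 0.072) with the fibroblast covariate. T changed by -5.37 and the growth factor Fgf8 by -4.30. Only 1 of 18 primitive endoderm genes, Amn, was called (-0.93, adjusted p = 0.0319; 0 adjusted over the list alone; adjusted p = 0.939). Of 16 MHC class I genes 9 fell and 0 rose (11 and 1 adjusted over the list alone; median -0.95, adjusted p = 0.00122; adjusted p = 0.585 with an estimated correlation). Of 23 cholesterol synthesis genes 13 fell and 1, Ebp, rose (15 and 1 adjusted over the list alone; median -0.36, adjusted p = 0.000577; adjusted p = 0.687 with an estimated correlation).

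Prelp rose in B6J as well, from 1.12 ± 0.114 to 25.9 ± 7.58 CPM (log2 fold change 4.54), Col10a1 by 4.17 and C1qtnf3 by 3.85. Of 20 fibroblast markers 12 rose and 0 fell (15 and 0 adjusted over the list alone; median 0.83, camera adjusted p = 0.000582; adjusted p = 0.825 with an estimated correlation). The mean log2 CPM of these markers was 5.90, 6.24 and 6.01 in replicates 1 to 3 of B6J with DMSO and 6.56, 6.94 and 7.20 with the inhibitor. Of 31 Hox genes 4 rose in B6J (Hoxc6, Hoxa9, Hoxc8, Hoxb5), 1 of them adjusted over the list alone, and others fell, among them Hoxd1 and Hoxb1 (median 0.49, adjusted p = 0.167). With the covariate the median of the cholesterol genes in B6J was -0.13 (adjusted p = 0.0605).

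Between the 2 responses, 1731 genes were higher in both (422.5 would be shared by independent lists), 1907 were lower in both (500 for independent lists) and 45 changed in opposite directions (920 for independent lists).

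**Figure D2:**
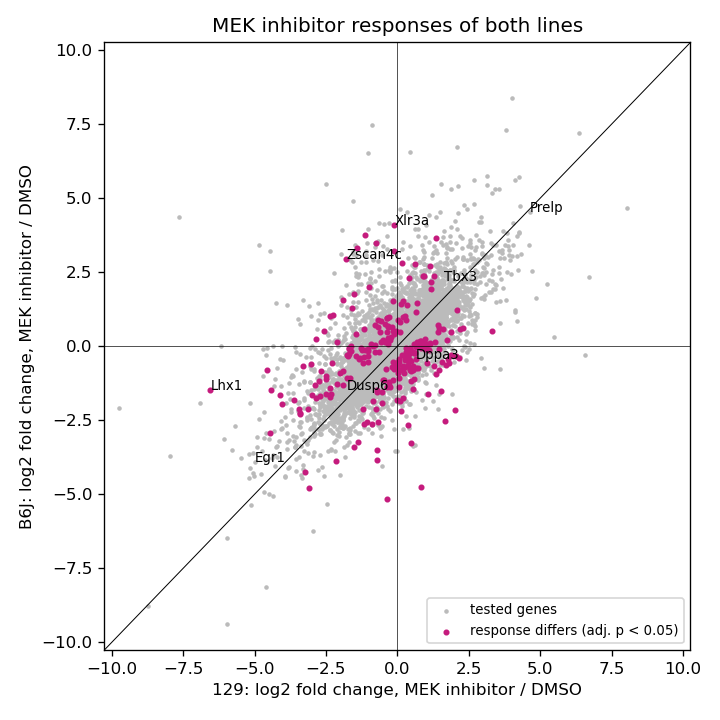
Each point is a tested gene, with its log2 fold change (MEK inhibitor over DMSO) in 129 on the x axis and in B6J on the y axis; the diagonal marks equal responses. Magenta points are the 246 genes whose response differed between the backgrounds (adjusted p under 0.05), and named genes are labelled.

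The test of the difference in response asks which genes the inhibitor moved differently in the 2 backgrounds, with positive values where the change in B6J was the higher one. Primitive streak genes were among them. Lhx1 fell from 20.2 to 0.216 CPM in 129 and stood at 0.444 ± 0.149 and 0.159 ± 0.0496 CPM in B6J, a difference of 5.07 on the log2 scale (SE 0.66, adjusted p = 0.00454). Eomes, a T-box factor, fell from 31.4 to 3.86 CPM in 129 and from 8.82 ± 1.5 to 5.78 ± 0.131 CPM in B6J (difference 2.41, SE 0.23, adjusted p = 0.00115). Xlr3a was at 11.7 ± 0.960 and 10.8 ± 2.58 CPM in 129 and rose from a low level in B6J (4.21, SE 0.54, adjusted p = 0.0042; 0.0526 with limma-voom). There were 246 such genes, 118 with a positive and 128 with a negative difference. Without single libraries the count was 586, 98 and 126 (replicates 1, 2 and 3 of 129 with DMSO), 127 and 110 (replicates 2 and 3 of 129 with the inhibitor), 119, 102 and 146 (replicates 1 to 3 of B6J with DMSO) and 95, 73 and 148 (replicates 1 to 3 of B6J with the inhibitor). DESeq2 called 798.

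Of 17 genes of mesoderm and primitive streak 4 had a positive difference (Eomes, Lhx1, Gsc, Mixl1), with 6 positive and 2 negative adjusted over the list alone. Gsc differed by 3.28 (adjusted p = 0.00736) and Mixl1 by 2.92 (adjusted p = 0.00854; 0.0688 with limma-voom). Of 31 genes of the 2-cell-like state 4 differed (Pramef25, Zscan4c, Zscan4d, Gm5662), all positive, and 24 did so adjusted over the list alone, while DESeq2 called 16 and limma-voom 0. Their median was 3.70 (camera adjusted p = 3.12e-12; adjusted p = 0.585 with an estimated correlation). Zscan4c was at 5.04 ± 3.29 and 1.45 ± 0.832 CPM in 129 and at 0.145 ± 0.0466 and 1.12 ± 0.273 CPM in B6J (difference 4.74, SE 0.93, adjusted p = 0.0337). Of the 12 fits that leave out 1 library these 4 calls were kept without replicate 1 of 129 with DMSO, and that of Zscan4c also without replicate 1 of 129 with the inhibitor (highest adjusted p = 0.124, for Gm5662). Of 47 germline genes 1 had a positive difference (Xlr3a) and 2 (2 and 2 adjusted over the list alone) a negative one, Rhox6 (-2.18, adjusted p = 0.00227) and Rhox9 (-2.17, adjusted p = 0.00166). Kbtbd11, a gene with Kelch and BTB domains, differed by -3.03 (adjusted p = 0.00246).

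Among genes of DNA methylation and its protection, Dppa3 rose in 129 from 10.7 ± 1.69 to 16.7 ± 2.58 CPM, and was at 57.3 ± 5.46 and 42.1 ± 2.63 CPM in B6J (difference -1.10, SE 0.19, adjusted p = 0.0187). That call was lost without replicate 2 of 129 with DMSO, replicate 1 of B6J with DMSO or replicate 2 of B6J with the inhibitor (adjusted p = 0.0583, 0.0518 and 0.0669). Gadd45a, a DNA damage and repair gene, differed by -1.19 (adjusted p = 0.00572) and Setdb1 by -0.80 (adjusted p = 0.00264). Dnmt3a differed by -0.84 (SE 0.23, adjusted p = 0.108) and Dnmt3l by -0.71 (adjusted p = 0.211). With the replicate number as a block the adjusted p of Dnmt3a was 0.0241, and without replicate 1 of 129 with DMSO that of Dnmt3l was 0.0247. The difference was 0.03 for Dnmt3b (adjusted p = 0.955), 0.06 for Uhrf1 (0.872), 0.09 for Dnmt1 (0.811), -0.01 for Prdm14 (0.997), 0.28 for Nanog (0.704) and 0.29 for Dusp6 (0.313). Egr1 differed by 1.08 (adjusted p = 0.0856; 0.0101 without replicate 1 of 129 with DMSO) and its relative Egr3 by 2.08 (adjusted p = 0.0118). For this difference edgeR called 0 of the 60 imprinted genes (9 positive and 6 negative at an unadjusted p under 0.05, 5 and 3 adjusted over the list alone, 5 and 4 in DESeq2), 0 of the 23 cholesterol genes (2 positive unadjusted, 0 in DESeq2) and 0 of the 20 fibroblast markers (0 unadjusted, 0 in DESeq2), both also 0 adjusted over the list alone. In limma-voom 0 were called in each. The fibroblast list (median -0.21, adjusted p = 0.109) was called for this difference with the replicate number as a block (-0.27, adjusted p = 0.00385), without both 129 libraries numbered 1 (-0.41, adjusted p = 0.00175) and without replicate 1 of 129 (-0.64, adjusted p = 6.16e-05) or of B6J (adjusted p = 0.0353) with DMSO or replicates 2 and 3 of 129 and 3 of B6J with the inhibitor (0.0282, 0.042 and 0.0169). It was 0.02 without replicate 1 of 129 with the inhibitor and 0.01 with the covariate.

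In DMSO the 2 backgrounds differed in single genes with near all-or-none expression and in several gene groups. The oligodendrocyte transcription factor Olig2 was at 29.5 ± 4.30 CPM in B6J against 0.0197 ± 0.0172 CPM in 129. Zfp42 (Rex1), a standard marker of naive ES cells, was at 35.7 ± 0.843 CPM in B6J and 289 ± 33.0 CPM in 129, while Dppa3 was at 57.3 ± 5.46 and 10.7 ± 1.69 CPM. Ubd, a ubiquitin-like protein gene, was at least 399-fold higher in B6J, whereas the guanylate-binding protein gene Gbp2b was at least 10900-fold, Ugt2b34 at least 643-fold and S100g at least 620-fold lower, their B6J or 129 libraries having no counts. There were 3468 genes differentially expressed, 1722 higher and 1746 lower in B6J. A fit of these 2 groups alone called 2247.

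The log2 difference in DMSO (B6J minus 129) was 10.47 (SE 0.44, adjusted p = 5.74e-08) for Olig2, -8.36 for Xlr3a and -7.65 for the homeobox gene Crxos. Of 20 naive genes 2 were higher (Dppa3, Dppa5a) and 8 lower in B6J, the same numbers adjusted over the list alone. Their median was -0.30 (camera adjusted p = 0.0297; adjusted p = 0.855 with an estimated correlation). That call was lost without replicate 2 or 3 of 129 with DMSO (medians -0.18 and -0.16, adjusted p = 0.0667 and 0.108) and without replicate 3 of B6J with DMSO (adjusted p = 0.097), and with the fibroblast covariate (median -0.08, adjusted p = 0.153). The genes included Zfp42 (-3.02, SE 0.11, adjusted p = 1.29e-08), Fbxo15 (-1.29) and Tbx3 (-1.002). Nanog was at 453 ± 132 and 370 ± 35.1 CPM (-0.29, adjusted p = 0.272; -0.51 with adjusted p = 0.0022 without replicate 1 of 129). Of 31 genes of the 2-cell-like state 25 were lower and 0 higher in B6J (30 and 0 adjusted over the list alone; median -3.84, adjusted p = 6.03e-12; adjusted p = 0.585 with an estimated correlation), with Zscan4c at -5.11. In replicate 1 of 129 the summed list was at 9.8 CPM against 64.7 and 68.8 CPM in replicates 2 and 3. Of 47 germline genes 22 were lower and 5 higher (Ddx4, Piwil2, Rhox9, Tdrd1, Rhox6), with 23 and 5 adjusted over the list alone and a median of -0.64 (adjusted p = 4.93e-06; adjusted p = 0.585 with an estimated correlation). Of 17 genes of mesoderm and primitive streak 10 were lower and 2 (Hand1, Wnt3a) higher (10 and 3 adjusted over the list alone; median -1.83, adjusted p = 0.0026; adjusted p = 0.585 with an estimated correlation), with Lhx1 at -5.51. The list of 18 primitive endoderm genes, 7 of them lower and 1 (Amn) higher, was not called (median -2.19, adjusted p = 0.0642; 0.00401 without replicate 2 and 0.0028 without replicate 3 of 129). Adjusted over the list alone 11 were lower and 1 higher. DESeq2 called 2 lower and 1 higher, and limma-voom 1 and 1. The median was 0.155 (adjusted p = 0.954) without replicate 1 of 129, and without both 129 libraries numbered 1 there were 7 higher and 5 lower (median 0.154, adjusted p = 0.839). Of 22 ATF4 and amino acid stress genes 12 were higher and 1 (Slc7a11) lower (16 and 1 adjusted over the list alone; median 0.40, adjusted p = 1.99e-06; adjusted p = 0.585 with an estimated correlation), and Atf4 itself was higher by 1.03. Of 23 cholesterol synthesis genes 8 were higher and 2 (Stard4, Ebp) lower (13 and 2 adjusted over the list alone; median 0.29, adjusted p = 0.00295; adjusted p = 0.744 with an estimated correlation).

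Among methylation genes in DMSO, Dnmt3a was higher in B6J (log2 difference 0.95, SE 0.16, adjusted p = 0.0016), as were Dnmt3l (0.90, adjusted p = 0.00307) and the DNA glycosylase gene Tdg (1.42, adjusted p = 3.52e-07), which excises oxidised methylcytosine. The difference was 0.23 for Dnmt3b (adjusted p = 0.13), 0.09 for Dnmt1 (0.464) and 0.19 for Uhrf1 (0.111). Of 14 writers 5 were higher (Ahcy, Dnmt3a, Dnmt3l, Cdca7, Pcna) and 1, Uhrf2, lower, the same numbers adjusted over the list alone (camera adjusted p = 0.057; 0.0378 without replicate 2 and 0.0338 without replicate 3 of 129). Ahcy and Pcna share sequence with single-exon copies. Of 16 demethylation genes 4 were higher (Tdg, Dppa3, Gadd45a, Apex1) and 1, Apobec1, lower, with 4 and 2 adjusted over the list alone (adjusted p = 0.232). Of 18 genes of imprint protection 3 were higher (Dppa3, Setdb1, Ehmt2) and 0 lower in edgeR, with 5 and 0 adjusted over the list alone (adjusted p = 0.151). Unadjusted, edgeR found 6 higher and 0 lower, and DESeq2 called 5 and 0. Of 60 imprinted genes 6 were higher and 11 lower (7 and 14 adjusted over the list alone; adjusted p = 0.276). The maternally expressed RNA Meg3 was at 215 ± 28.0 CPM in 129 and at 42.5 ± 16.7 CPM in B6J (-2.34).

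With the inhibitor Olig2 was at 39.5 ± 1.69 CPM in B6J and 0.0474 ± 0.0485 CPM in 129. Zfp42 was at 67.4 ± 8.23 and 481 ± 24.6 CPM, and Dppa3 at 42.1 ± 2.63 and 16.7 ± 2.58 CPM. There were 3053 genes differentially expressed, 1479 higher and 1574 lower in B6J. Between both media 881 genes were higher in B6J in each (153.2 for independent lists), 876 lower in each (165.3 for independent lists) and 30 opposite (318.3 for independent lists).

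With the inhibitor the log2 difference (B6J minus 129) was 9.60 (adjusted p = 4.14e-08) for Olig2, -7.32 for Crxos and -7.23 for Kbtbd11, and Gbp2b was at least 586-fold and Ugt2b34 at least 9.07-fold lower. It was -2.84 (adjusted p = 2.32e-08) for Zfp42 and 1.33 (adjusted p = 4.69e-05) for Dppa3. Of 47 germline genes 24 were lower and 1, Ddx4, higher (30 and 1 adjusted over the list alone; median -1.05, camera adjusted p = 7.08e-10; adjusted p = 0.585 with an estimated correlation). Of 31 genes of the 2-cell-like state 4 were lower (Pramel6, Pramel7, Tdpoz4, Gm21761) and 1, Tcstv1, higher, the same numbers adjusted over the list alone (median -0.76, adjusted p = 0.196; 0.024 without replicate 1 of 129 with the inhibitor). Of 23 cholesterol synthesis genes 13 were higher and 1, Stard4, lower (14 and 1 adjusted over the list alone; median 0.34, adjusted p = 5.84e-05; adjusted p = 0.614 with an estimated correlation). Of 14 methylation writers 4 were higher (Ahcy, Pcna, Cdca7, Uhrf1) and 0 lower in edgeR (7 and 0 unadjusted, 5 and 0 adjusted over the list alone and in DESeq2). Their median was 0.19 (adjusted p = 0.00855; adjusted p = 0.585 with an estimated correlation), with a median of 0.12 without replicate 1 of 129 with the inhibitor. Uhrf1 differed by 0.25 (adjusted p = 0.044), a call lost in 5 of the 6 fits that leave out 1 library and kept without replicate 2 of 129 (highest adjusted p = 0.0922). The difference was 0.11 for Dnmt3a (adjusted p = 0.721), 0.26 for Dnmt3b (0.0971), 0.20 for Dnmt3l (0.502) and 0.18 for Dnmt1 (0.16), and Tdg was higher by 1.51. Of 60 imprinted genes 13 were lower and 4 (Usp29, Peg3, Nnat, Ppp1r9a) higher (13 and 6 adjusted over the list alone; adjusted p = 0.111). Of 17 genes of mesoderm and primitive streak 2 (Kdr, T) were lower and 1, Eomes, higher, with 4 and 2 adjusted over the list alone (adjusted p = 0.25). Of the 20 fibroblast markers 0 were called in edgeR, 0 at an unadjusted p under 0.05, 0 adjusted over the list alone and 0 in DESeq2 and limma-voom (median 0.07, adjusted p = 0.753).

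**Figure D3:**
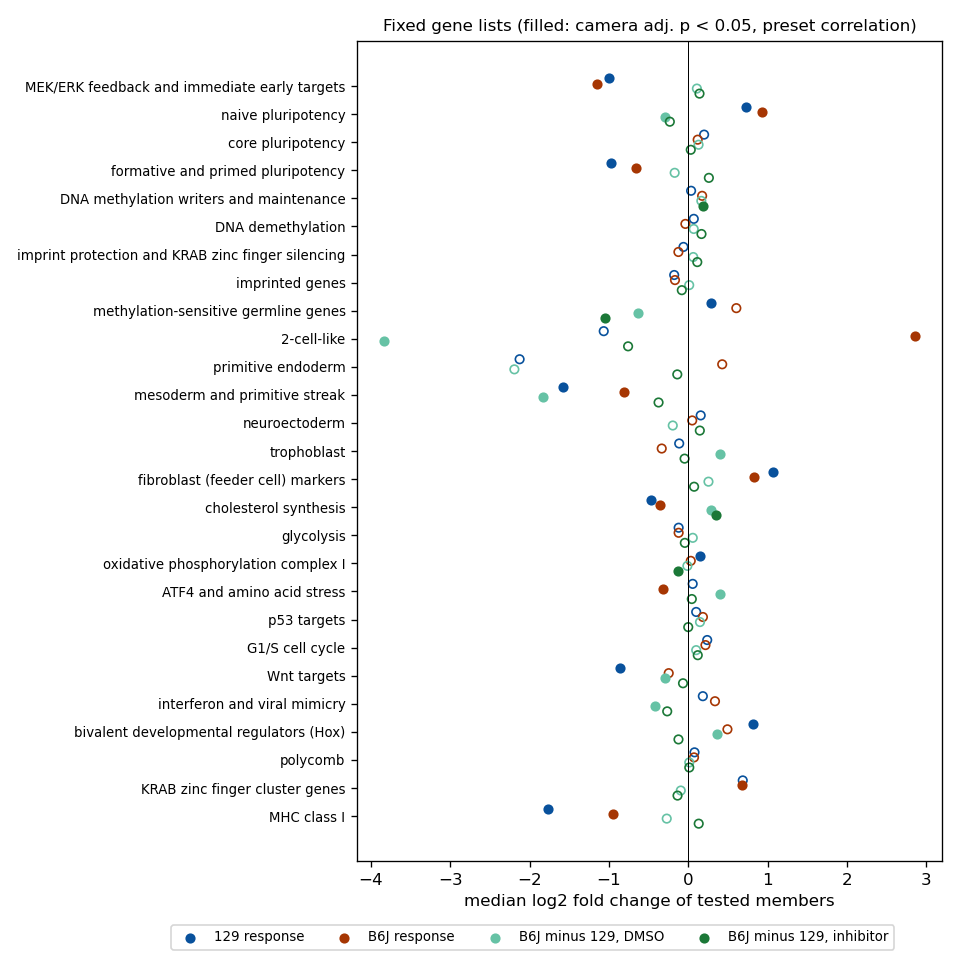
Each line of the plot is a gene list and each point the median log2 fold change of its tested members (x axis) in 1 of 4 contrasts, told apart by colour; filled points have a camera adjusted p under 0.05 at the preset correlation. The 2-cell-like list lies at 2.86 for the B6J response and at -3.84 for the difference between backgrounds in DMSO.

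Positions in GRCm38 (GENCODE M21) of the genes at the centre of these comparisons, all protein-coding, were as follows. Egr1 (ENSMUSG00000038418) lies on chromosome 18 from 34859823 to 34864984. Dnmt3a (ENSMUSG00000020661) spans 3806007 to 3914443 of chromosome 12 and Dnmt3b (ENSMUSG00000027478) 153649450 to 153687730 of chromosome 2. Dppa3 (ENSMUSG00000046323) lies on chromosome 6 from 122626410 to 122630272 and Zfp42 (ENSMUSG00000051176) on chromosome 8 from 43295063 to 43306980.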

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

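The tests of the 3 patterns weighed here (fibroblast markers, 2-cell-like genes, single-exon copies) and the fits with the fibroblast covariate were chosen after the results were seen; the splits of the libraries and the fits leaving out 1 library were planned, but how the splits for the difference in response are read was changed after their counts were seen.

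The results listed here stand out because the response to the inhibitor differed between the 2 backgrounds in a test of that difference (B6J minus 129, edgeR), which called 246 genes. Held in all 12 fits that leave out 1 library were Lhx1 (5.065), Eomes (2.411), Gsc (3.276), Mixl1 (2.923), the X-linked gene Xlr3a (4.206), Rhox6 (-2.177), Rhox9 (-2.173), Gadd45a (-1.188), Setdb1 (-0.799), the cystathionine enzyme Cth (-0.625), the immediate early gene Egr3 (2.078), tapasin (Tapbp, 0.858), Kbtbd11 (-3.031) and Apln (3.734). Dppa3 (-1.097) was lost in 3 of the 12 fits (without replicate 2 of 129 with DMSO, replicate 1 of B6J with DMSO and replicate 2 of B6J with the inhibitor, adjusted p up to 0.0669) and Gata3 (-1.678), a trophoblast factor, in 3 (without replicate 3 of 129 and replicates 1 and 2 of B6J with the inhibitor, up to 0.0574). Atf4 (-0.475), the transcription factor of the amino acid response, was lost in 5 (without replicates 2 and 3 of 129 with DMSO, replicate 2 of B6J with DMSO and replicates 1 and 2 of B6J with the inhibitor, adjusted p up to 0.084). Its target Chac1 (-1.011) was lost in 8, kept without replicates 1 and 2 of 129 with DMSO, replicate 3 of 129 with the inhibitor and replicate 1 of B6J with DMSO (adjusted p up to 0.0902). Trib3 (-0.895) was lost in 10, kept without replicate 1 of 129 with DMSO and replicate 3 of 129 with the inhibitor (up to 0.12). Uhrf2 (0.574) was lost in 10, kept without replicate 1 of 129 with DMSO and replicate 3 of B6J with the inhibitor (up to 0.127). The keratin gene Krt7 (-1.38) was lost in 10, kept without replicate 1 of 129 and replicate 2 of B6J with DMSO (up to 0.104). Zscan4c (4.736) was lost in 10, kept without replicate 1 of 129 with DMSO or with the inhibitor (up to 0.0972). The calls of Tap2 (1.492), Zscan4d (4.715), Gm5662 (4.9) and Pramef25 (4.209) were lost in 11 and kept without replicate 1 of 129 with DMSO (adjusted p up to 0.105, 0.103, 0.124 and 0.0995). With the replicate number as a block the calls of Uhrf2, Trib3, Tap2 and Krt7 were lost (adjusted p = 0.0934, 0.11, 0.11 and 0.0779).

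Of the 27 gene lists, 10 also differed in response by camera at the preset correlation, and 0 with an estimated correlation. Kept in every fit leaving out 1 library were the 2-cell-like list (median 3.703, adjusted p = 3.12e-12; adjusted p = 0.585 with an estimated correlation), ATF4 and amino acid stress (-0.363, 7.05e-08; 0.585), trophoblast (-0.558, 0.000552; 0.585), Wnt targets (0.423, 0.0026; 0.585), MHC class I (0.499, 8.9e-05; 0.585) and the Hox genes (-0.48, 0.000577; 0.723). Members with a positive and a negative difference numbered 0 and 4 (ATF4; 0 and 7 adjusted over the list alone), 0 and 2 (trophoblast; 0 and 6), 1, Axin2, and 0 (Wnt; 3 and 0) and 2 and 0 (MHC class I; 4 and 0). For the Hox, formative, primitive endoderm and interferon lists edgeR called 0 (unadjusted 0 and 5, 7 and 2, 6 and 0, 5 and 0; DESeq2 0 and 1, 4 and 1, 0 and 0, 2 and 0; limma-voom 0; adjusted over the list alone 0 and 0, 6 and 2, 0 and 0, 2 and 0). The Hox median was -0.811, -0.31 and -0.295 without replicates 1, 2 and 3 of 129 with DMSO and -0.245 without replicate 1 of 129 with the inhibitor. The formative list (0.407, 0.0147; 0.729) was lost without replicates 2 and 3 of 129 with DMSO (0.399 and 0.26, adjusted p = 0.0589 and 0.0576) and replicate 3 of B6J with the inhibitor (0.274, adjusted p = 0.139). The mesoderm list (0.426, 0.0146; 0.585) was lost without replicate 1 of 129 (0.075, adjusted p = 0.0675) and replicate 3 of B6J (-0.032, adjusted p = 0.0966) with the inhibitor; its median was 0.199 without replicate 3 of 129 with DMSO, 0.049 and 0.136 without replicates 1 and 2 of B6J with DMSO and 0.216 without replicate 2 of B6J with the inhibitor. The primitive endoderm list (1.762, 0.0413; 0.866) was -0.377 (adjusted p = 0.795) without replicate 1 of 129 with DMSO and 2.694 without replicate 1 of 129 with the inhibitor. It was lost without replicates 2 and 3 of 129 with the inhibitor (adjusted p = 0.143 and 0.134), replicates 1 to 3 of B6J with DMSO (0.0536, 0.0535 and 0.0675) and replicate 3 of B6J with the inhibitor (0.139). The interferon list (0.367, 0.0413; 0.655) was lost without replicates 2 and 3 of 129 with DMSO (adjusted p = 0.0915 and 0.0647) or with the inhibitor (0.125 and 0.0839), and without replicate 3 of B6J with DMSO or with the inhibitor (0.163 and 0.0768).

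Fibroblast markers were higher with the inhibitor in both backgrounds, with 15 and 12 of 20 called. In ratio to the others 9 markers changed in 129 and 13 in B6J (limma; Dcn 1.17 and 1.04, Tagln -1.40 and -1.28). Ratios cannot test a higher fibroblast share, which shifts them if ES cells express some markers. RNA of another cell type in the libraries remains open: within groups the mean of the Hox genes, which ES cells express little, followed the marker mean over 12 libraries with a Pearson r of 0.929 (permutation p = 0.00926, adjusted p = 0.0278, shuffling within groups with the 129 pairs kept together; 0.881 without replicate 1 of 129 with DMSO and replicate 1 with the inhibitor) and a Spearman rho of 0.825 (permutation p = 0.0139, adjusted p = 0.0346). Of the 3 relations tested, the naive genes gave r = -0.892 (permutation p = 0.0231, adjusted p = 0.0346; rho = -0.853, permutation p = 0.0231; -0.624 without 2 libraries) and Xist r = 0.235 (permutation p = 0.356; rho = 0.245, permutation p = 0.449; 0.205 without 2 libraries). A candidate explanation is a shifting amount of differentiated or feeder cells, with or without a change in their own expression. Col1a1 was at 792 ± 302 CPM in 129 with DMSO, and the labels name no feeder layer and no sort. An effect of the inhibitor on matrix genes in the ES cells themselves was not tested apart.

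Of 31 genes of the 2-cell-like state 4 differed in response (DESeq2 16, limma-voom 0, list median 3.703). The summed list was at 9.8 CPM in replicate 1 of 129 with DMSO and 64.7 and 68.8 in replicates 2 and 3. Reads split between members of the list would stay inside its summed counts, whose difference in response was 3.286 (SE 0.767, adjusted p = 0.0648), with 2.39, 2.39 and 2.6 CPM in B6J with DMSO against 15.3, 16.7 and 14.4 CPM with the inhibitor. A strain variant against the reference would act in both media, so the list being lower in B6J in DMSO (-3.838) does not test it. Reads dropped as ambiguous or given to relatives off the list were not tested and stay open. A background difference in how often cells enter this state may underlie the pattern. Line and background cannot be separated, and with the covariate the median was 2.99.

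Single-exon gene copies were higher in 129 than in B6J: of 83 tested copies with a tested parent gene, 16 copies of 15 parents were higher in 129 by at least 2 on the log2 scale and 1 was higher in B6J. Reads shared between copy and parent would leave their sum nearly equal: 5 of the 15 sums differed by less than 0.3 (Ahcy 0.11, Pcna -0.02, Eif3j1 -0.11, Cyb5d1 -0.24, Dcun1d1 -0.22), while the median size was 1.18, with -5.74 to -4.71 for the 4 parents in pairs with a 2-cell-like gene and a median size of 0.416 for the other 11 parents. A first set of 5 pairs picked by eye (median 0.11) was replaced. Sequence defined the 83, copy expression the 16. Shared reads and higher transcription of the copies alone cannot be told apart, since 5 of the 15 parents (33.3%, against 10.4% of all genes) were higher and 7 lower in B6J, and dropped reads would leave sums unequal.

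Other splits of the same libraries were counted to see how often they call as many genes. For the response in 129 the real split called 5930 genes and 1 of 10 splits (the real one) gave as many, the highest other calling 0; for B6J it was 5166, 1 of 10 and 0. For the difference between backgrounds it was 3468, 1 of 10 and 26 in DMSO, and 3053, 1 of 10 and 0 in the inhibitor. With 10 splits no share under 0.05 is possible. In 129, where the numbers pair the libraries, 4 of the 10 splits part all 3 pairs, and the other 3 of these called 0. For the difference in response 4 of 100 splits, the real one included, called as many as 246; the others called 5191, 1322 and 331. Most other splits mix the backgrounds within groups and so put the difference between them into the spread, and the count does not decide whether chance can be excluded. The split with 5191 exchanges the backgrounds in the inhibitor groups only and so points to a structure of the samples, the difference between backgrounds, and not to the response.

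Single libraries also stood apart. Y-linked transcripts were low in replicate 1 of B6J with DMSO, with Ddx3y at 2.19 CPM against 18.9 and 17.3, Uty at 4.6 against 21.2 and 19.4 and Eif2s3y at 13.5 against 53.7 and 50.9 in replicates 2 and 3. In replicate 1 of 129 with DMSO Kdm5d was at 6.23 CPM against 0.319 and 0.224.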

How the results depend on the processing

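The tests with the fibroblast covariate, without both 129 libraries numbered 1 and with halved counts were chosen after the data were seen; all other alternatives were planned. Of 176 gene results and 135 list results, 139 and 46 kept their direction and their side of the threshold under every alternative other than the estimated correlation between genes. In 8 genes and 57 lists the direction turned under some alternative, in 1 and 8 of these where the value was called in either fit and in 7 and 49 where it was called in neither. The largest shift of the median of all genes was 0.046 on the log2 scale, in 129 with upper quartile scaling. Depth limits low genes most, with a floor of 3 counts over a group at 0.0115 to 0.0147 CPM. Low values are mostly even, and if mates were counted separately their counting error is larger than the counts show. Halved counts called 254 genes for the difference in response (243 shared) and lost the call of Gm5662 there (adjusted p = 0.0567).

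Counts moved by more than 1.5 times as follows. At an adjusted p under 0.01 there were 3546 genes for the response in 129, 3161 in B6J and 58 for the difference in response. Between backgrounds there were 1864 in DMSO and 1746 in the inhibitor, and the overlap of the responses held 2178. With a minimum 2-fold change the 5 contrasts held 2219, 2043, 140, 1392 and 1086. Both follow from the stricter threshold. For the difference in response, with 246 genes called, DESeq2 called 798 (246 shared), limma-voom 163 (160 shared), the covariate fit 815 (246 shared) and the fit without both 129 libraries numbered 1 608 (230 shared); the cause was not tested. Leaving out 1 library gave 73 (without replicate 2 of B6J with the inhibitor) to 586 (without replicate 1 of 129 with DMSO, 245 shared). The fit of the DMSO groups alone called 2247 genes between backgrounds, with fewer libraries to estimate the spread. With an estimated correlation 0 of the 45 list calls remained.

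With the replicate number as a block the counts were 6216, 5507, 238, 3024 and 2736 in the same order, and 51 list tests were called; 163 of the 238 were shared with the 246. Called with the block and not without it, all libraries kept, were the 2-cell-like list in 129, the fibroblast list for the difference in response (-0.266) and the Hox list in B6J (adjusted p = 0.029). The block also called the primitive endoderm list between backgrounds in DMSO (-1.508, adjusted p = 0.0363) and the G1/S list in both responses (adjusted p = 0.0354 and 0.048); some of these were also called under other alternatives. Among named genes the block gained Dnmt3a in 129 and for the difference in response, and lost Uhrf2, Trib3, Tap2 and Krt7 for that difference, Gata6 in 129 (adjusted p = 0.0889) and Uhrf1 between backgrounds in the inhibitor (adjusted p = 0.083). It changed no other call of a named gene or list. Outside 129 the numbers did not pair: same-numbered libraries correlated by -0.188, 0.0883 and -0.17 in B6J, by -0.0579, 0.00589 and -0.0732 across backgrounds in DMSO and by -0.32, 0.0161 and -0.094 in the inhibitor. Every 129 library and 1 of 6 B6J libraries correlated best with its own number.

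Directions turned for results called in either fit as follows, and the cause was not tested. With the covariate Zscan4c in 129 was 0.777, the 2-cell-like list in 129 1.65, the fibroblast list in 129 -0.018 and the Hox list in 129 -0.127. The covariate is itself the mean of the fibroblast list. It also gave -1.564 for the primitive endoderm list in B6J and -0.3 for the germline list in the difference in response. That germline list, at 0.024 with all libraries, ran from -0.173 to 0.099 with 1 library left out. For the same difference the primitive endoderm list ran from -0.377 to 2.694, and was -0.088 without both 129 libraries numbered 1. The mesoderm list ran from -0.032 to 0.567. Between backgrounds in DMSO the trophoblast list ran from -0.117 to 0.777.

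Values called in neither fit turned as follows, and the cause was not tested. With the covariate Dnmt3a was 0.138 in 129 and the lists there were -0.016 (demethylation), 0.297 (imprint protection), 0.01 (glycolysis), -0.028 (ATF4) and -0.03 (p53). In B6J it gave -0.305 for Dnmt3l, 0.144 for imprint protection, -0.013 for complex I and -0.257 for Hox. For the difference in response it gave -0.015 for Dnmt3b, -0.02 for demethylation, -0.094 for imprint protection, 0.009 for fibroblast and -0.381 for KRAB genes. In DMSO it gave 0.044 for formative, -0.073 for imprinted, 0.102 for neuroectoderm, -0.026 for fibroblast and 0.501 for KRAB genes, and in the inhibitor 0.017 for Nanog. Without both 129 libraries numbered 1 the values in 129 were -0.166 (neuroectoderm), 0.475 (trophoblast), -0.047 (ATF4) and -0.238 (interferon). For the difference in response they were 0.019 (core), -0.017 (imprint protection), -0.002 (germline), 0.493 (neuroectoderm) and -0.037 (KRAB). In DMSO they were -0.05 (demethylation), 0.154 (primitive endoderm) and 0.006 (complex I), and in the inhibitor -0.031 (Dnmt3a), -0.019 (core), 0.074 (primitive endoderm), 0.026 (trophoblast), 0.025 (glycolysis), 0.086 (Hox) and -0.033 (polycomb). With no filter and the stricter filter trophoblast in 129 was 0.477 and 0.516, imprinted genes in DMSO -0.02 and -0.03 and polycomb there -0.003 and -0.013, and for the difference in response germline was -0.021 and -0.014 and G1/S and polycomb both 0.004 and 0.001. The stricter filter gave 0.087 and 0.094 for demethylation and trophoblast in B6J, 0.025 for neuroectoderm in DMSO and -0.004 for polycomb in the inhibitor. Halved counts gave -0.008 for germline in the difference in response and -0.011 for imprinted genes in DMSO, the replicate block 0.008 for neuroectoderm in the difference in response and 0.099 for KRAB genes in the inhibitor, and RLE scaling 0.002 for p53 in the inhibitor.

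With 1 library left out, values in 129 ran from -0.002 to 0.166 (Dnmt1), -0.019 to 0.323 (Tet1), -0.01 to 0.092 (writers), -0.151 to 0.038 (imprint protection), -2.611 to 0.1 (primitive endoderm), -0.322 to 0.549 (neuroectoderm), -0.089 to 0.517 (trophoblast), -0.008 to 0.077 (ATF4), -0.114 to 0.352 (interferon) and -0.014 to 1.029 (KRAB). In B6J they ran from -0.103 to 0.035 (demethylation), -0.057 to 0.337 (neuroectoderm) and -0.216 to 0.068 (trophoblast). For the difference in response they ran from -0.055 to 0.116 (Dnmt3b), -0.132 to 0.012 (MEK/ERK), -0.169 to 0.023 (core), -0.105 to 0.061 (imprint protection), -0.106 to 0.013 (imprinted), -0.152 to 0.382 (neuroectoderm), -0.637 to 0.022 (fibroblast), -0.036 to 0.054 (G1/S), -0.059 to 0.003 (polycomb) and -0.307 to 0.692 (KRAB). In DMSO they ran from -0.049 to 0.114 (demethylation), -0.039 to 0.029 (imprinted), -2.685 to 0.155 (primitive endoderm), -0.3 to 0.034 (neuroectoderm), -0.038 to 0.111 (glycolysis), -0.081 to 0.021 (complex I), -0.008 to 0.052 (polycomb) and -0.487 to 0.211 (KRAB). In the inhibitor they ran from -0.039 to 0.193 (Dnmt3a), -0.082 to 0.034 (Nanog), -0.008 to 0.259 (MEK/ERK), -0.044 to 0.04 (core), -0.315 to 0.067 (primitive endoderm), -0.124 to 0.025 (trophoblast), -0.111 to 0.288 (fibroblast), -0.09 to 0.015 (glycolysis), -0.013 to 0.076 (ATF4), -0.056 to 0.042 (p53), -0.118 to 0.021 (Wnt), -0.305 to 0.079 (Hox), -0.059 to 0.042 (polycomb) and -0.437 to 0.546 (KRAB).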

Other observations

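The list tests given here were fixed in advance; the genes named for counts of 5 or fewer and the genes with no counts in a group were chosen after their values were seen.

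Wnt targets fell in 129 with the inhibitor, with 9 of 14 lower and 2 higher over all genes and adjusted over the list alone (median -0.865, camera adjusted p = 0.00674; adjusted p = 0.585 with an estimated correlation; -0.578, adjusted p = 0.0731 with the fibroblast covariate). Sp5 fell (log2 fold change -1.93), while Notum, which inactivates Wnt ligands, rose by 1.61 and Bmp4 by 0.86. In B6J 5 fell and 1 rose, Notum by 2.23 (5 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.319). ATF4 and amino acid stress genes fell in B6J, 11 of 22 lower and 1, Nupr1 (0.64), higher (11 and 2 adjusted over the list alone; median -0.323, adjusted p = 0.0175; adjusted p = 0.761 with an estimated correlation). In 129 7 rose and 7 fell (7 and 8 adjusted over the list alone; adjusted p = 0.806). The list of complex I subunits was higher in 129, with 7 of 24 raised and 0 lowered by edgeR (unadjusted 9 and 0, DESeq2 9 and 0, limma-voom 7 and 0; 6 and 0 adjusted over the list alone). Its median was 0.146 (adjusted p = 0.0208; adjusted p = 0.866 with an estimated correlation), and 0.101 without replicate 1 of 129 with the inhibitor, where the call was lost (adjusted p = 0.146), as it was without both 129 libraries numbered 1 (0.074, adjusted p = 0.217) and with the fibroblast covariate (0.048, adjusted p = 0.449). In B6J Ndufb5 (0.39) and Ndufv1 (0.23) rose (1 adjusted over the list alone) and the list was not called (adjusted p = 0.354). Genes of the KRAB zinc finger cluster were called in B6J (median 0.679, adjusted p = 0.0302; adjusted p = 0.866 with an estimated correlation), with Zfp59 (1.58) and Zfp992 (0.94) of 27 higher and 1 adjusted over the list alone. That call was lost without replicate 1 of B6J with DMSO (adjusted p = 0.311) and replicates 1 and 2 with the inhibitor (0.259 and 0.0558). With all libraries the fry adjusted p of the list in B6J was 0.317. In 129 Zfp59 (1.01) and Zfp989 (1.29) rose (1 adjusted over the list alone) and the list was not called (adjusted p = 0.255; 0.0167 without replicate 1 of 129 with the inhibitor, 0.000404 with the covariate).

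Several other lists had called members while the list itself was not called in the responses given here. Of 14 trophoblast genes 6 rose and 6 fell in 129 (adjusted p = 0.981) and 3 and 6 in B6J (adjusted p = 0.128); the keratin Krt8 (-3.29 in 129 and -4.16 in B6J) fell and Gata3 (2.28 and 0.60) rose. Of 15 neuroectoderm genes 5 rose and 3 fell in 129 and 5 and 2 in B6J (adjusted p = 0.549 and 0.416). In 129 their median was 0.155 and their mean -0.239. Of 18 interferon genes 6 rose and 6 fell in 129 (adjusted p = 0.993; median 0.182, mean -0.268) and 5 and 3 in B6J (adjusted p = 0.284). Of 21 glycolysis genes 4 rose and 9 fell in 129 (adjusted p = 0.376) and 3 and 7 in B6J (adjusted p = 0.103; 0.0478 and 0.0318 without replicates 2 and 3 of B6J with DMSO). Of 28 G1/S genes 12 rose and 4 fell in 129 and 9 and 4 in B6J (adjusted p = 0.0618 in both; 0.0367 without replicate 1 of 129 with the inhibitor, and 0.0275 and 0.0393 without replicate 1 of B6J with DMSO and replicate 3 with the inhibitor; in 129 0.0354 with the replicate number as a block). Of 18 p53 targets 6 rose and 2 fell in 129 and 5 and 2 in B6J (adjusted p = 0.267 and 0.383). Of 18 polycomb genes 4 rose and 0 fell in 129 by edgeR (unadjusted and DESeq2 5 and 0, limma-voom 4 and 0), and 3 and 2 in B6J (adjusted p = 0.267 and 0.486). Adjusted over the list alone the numbers higher and lower in 129 and in B6J were 7 and 6, 3 and 6 (trophoblast), 6 and 4, 5 and 2 (neuroectoderm), 7 and 6, 5 and 3 (interferon), 5 and 10, 3 and 8 (glycolysis), 14 and 4, 11 and 4 (G1/S), 6 and 2, 5 and 3 (p53), 3 and 0, 2 and 2 (polycomb). With the covariate polycomb in 129 (0.363, adjusted p = 0.0183) and trophoblast in B6J (-1.097, adjusted p = 0.0383) were called. Of 31 2-cell-like genes in 129, Pramel7 (3.82) and Pramel6 (3.09) rose and Sp110 (-1.47) and Zscan4c fell (2 and 0 adjusted over the list alone; adjusted p = 0.301, median -1.067). The median was -1.558 without replicate 1 of 129 with DMSO, where the list was called (adjusted p = 7.75e-05), and with the replicate number as a block it was -0.829 (adjusted p = 0.0243). Zscan4c (-1.80) was not called without replicates 2 and 3 of 129 with DMSO (adjusted p = 0.0964 and 0.115), replicates 1 and 3 with the inhibitor (0.1 and 0.074), with limma-voom (0.0882), in a fit of the 129 groups alone (0.104) and with the covariate (0.777, adjusted p = 0.364).

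Between backgrounds in DMSO, interferon genes were lower in B6J, 8 of 18 and 0 higher by edgeR (unadjusted 9 and 1; 9 and 1 adjusted over the list alone), with a median of -0.419 (adjusted p = 0.0208; adjusted p = 0.585 with an estimated correlation). The call was lost without replicate 3 of B6J with DMSO (adjusted p = 0.0671). Wnt targets were lower (5 of 14, and 1 higher, the same numbers adjusted over the list alone; median -0.291, adjusted p = 0.0147; adjusted p = 0.585 with an estimated correlation) (Sp5 -1.94), and not called with the stricter filter (adjusted p = 0.0597). Trophoblast genes were higher (6 of 14, and 2 lower, or 6 and 3 adjusted over the list alone; median 0.398, adjusted p = 0.0302; adjusted p = 0.655 with an estimated correlation), Krt7 by 1.99. This call was lost without replicates 2 and 3 of 129 (-0.107 and -0.117, adjusted p = 0.0915 and 0.0664) and replicates 1 and 3 of B6J (0.114 and 0.13, adjusted p = 0.0617 and 0.0618), and with the covariate (0.204, adjusted p = 0.139). The Hox list was called with a median of 0.356 (adjusted p = 0.0138; adjusted p = 0.825 with an estimated correlation) although 0 of 31 passed by edgeR (unadjusted 4, DESeq2 0, limma-voom 0; 0 adjusted over the list alone), and lost without replicates 2 and 3 of 129 (adjusted p = 0.0771 and 0.0592) and replicate 2 of B6J (0.0608) and with the covariate (median 0.155, adjusted p = 0.235). Fibroblast markers there had a median of 0.253 (adjusted p = 0.0703; 0.035 with no filter), with 0 of 20 called by edgeR (unadjusted 1 higher, DESeq2 0, limma-voom 0; 0 adjusted over the list alone). Without both 129 libraries numbered 1, 13 were higher (median 0.658, adjusted p = 4.28e-05) and the Hox median was 0.739; without replicate 1 of 129 alone the marker median was 0.658 (adjusted p = 8.99e-05), and without replicate 1 of B6J 0.334 (0.0271). In the inhibitor the complex I list was lower in B6J (median -0.127, adjusted p = 0.033; adjusted p = 0.866 with an estimated correlation), with Ndufa5 (-0.54), Ndufa9 (-0.38) and Ndufa6 (-0.45) of 24 called, also adjusted over the list alone. It was lost without replicate 1 of 129 (-0.055, adjusted p = 0.281) and replicate 1 of B6J (adjusted p = 0.0798), and without both 129 libraries numbered 1 (-0.047, adjusted p = 0.386).

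As a label check, Nnt, not lower in B6J, was too low (0.58 to 1.2 CPM) to decide. Labelled male, all libraries held Xist (17.4 to 85.7 CPM) and Y-linked Eif2s3y (13.5 to 53.7). Besides Gbp2b, Ugt2b34 and S100g, Tdpoz4 had no counts in B6J, at least 19.8-fold below 129 with DMSO and 12.2-fold with the inhibitor. In DMSO Gm21761 and Pramef17 had none, at least 241-fold and 29.8-fold lower.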
